A study of Oncorhynchus kisutch with 70 samples.

How the data were processed

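The 70 arrays each measured RNA from one coho salmon olfactory rosette sample, in 14 groups of 5 taken from the sample titles. Per the labels' protocols, total RNA was purified with RNeasy columns and hybridised to an Agilent 44K salmonid array. The labels name the dye Cy5, while the files hold the green channel only. Per the file headers, the scans were read with Feature Extraction, which made each spot intensity by subtracting the background and removing a spatial and a multiplicative trend within the array, without scaling between arrays. The authors deposited a table of log2 values for the same arrays, with column medians of 5.91 to 6.42. Each of its columns had a rank correlation of at least 0.998 with mean minus background signal of its array. The medians were 6.24 to 6.38 in the mixture experiment, 6.30 to 6.42 with chlorpyrifos, 5.98 to 6.21 with malathion and 5.91 to 6.06 in the pLD pair. Its normalization and centring, and whether the experiments were normalized together, are not given in the sources used here. It served as an alternative.

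Each array held 43689 probes of 60 bases and 1417 control spots, which were left out. They had 42776 distinct sequences, and among the probes tested below 423 sequences occurred more than once. The 2430 spots marked as non-uniform outliers (0.0795% of all spots) were left out, 1682 of them among the tested probes; 1 saturated spot was kept. The signal was log2 processed signal minus the array's 75th percentile. A probe was tested when it was well above background on at least 4 of the 5 arrays of at least 1 group, which kept 33354 probes and left out 10335; 18679 were well above background on all 70 arrays. The 75th percentile differed by up to 5.41-fold between arrays, and a median of 72.1% of probes were well above background.

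All 70 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group, 56 residual degrees of freedom and moderated variances (prior degrees of freedom 3.10). Every adjusted p is limma's after Benjamini-Hochberg adjustment over the tested probes of 1 comparison, two-sided, at a threshold of 0.05. Each exposed group was compared with the control group of its own experiment. Further comparisons were the trend over the 4 equally spaced levels, the chlorpyrifos change minus the malathion change, the mixture change minus the sum of both, and the 4 control groups. The design, the comparisons, the rule for naming probes, 16 of the alternatives and the leave-one-out fits were set before the data were examined. Another 6 alternatives were chosen afterwards, from the brightness of the arrays, the slides that groups share, the share of probes well above background and the counts with normexp correction.

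Probe identities set the limits of the text. The files describe every probe as unknown, and of 409 probes that carry an accession as their identifier, 0 matched the 190265 accessions of the reference table used here. The gene lists fixed in advance could therefore not be tested, and the rule for named genes could not be applied as written. In its place the same rule was used without the gene-name condition, with at most 2 probes up and 2 down per comparison against a control. The probes were those past the threshold with the largest changes, well above background on all 5 arrays of 1 of the groups and with all 5 exposed arrays on the same side of the control mean. Where fewer than 5 probes met it, those with the smallest p were taken; of these, only those that passed the threshold are described, along with CUST_21187_PI417904088 in the pLD pair and at the lower chlorpyrifos level. For counts of 5 or fewer, called probes outside the rule were named after their values were seen.

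The fit was tested on simulated data with all 33354 probes, a seeded set of which was changed by known amounts. Every group had the same mean and spread per probe, with independent noise and no slide, scan-day or position differences. The runs thus differ only in the random draw and the group changed, and do not measure the sensitivity of the real comparisons. The fit recovered 62.7% of 2-fold and 93.9% of 4-fold changes in the Chlorpyrifos High run. In the Malathion Medium run it recovered 58.2% and 83.3%, in Mixture High 68.7% and 92.4%, and in the pLD pair 53.7% and 92.4%. Changes of 1.5-fold were recovered at 19.4%, 14.9%, 19.4% and 20.9%. The arrays came from 19 slides with 3 or 4 arrays each, scanned on 6 days. Slide, scan day and position on the slide were fitted as alternatives. Positions were uneven between groups, with all Chlorpyrifos Control and Mixture Control arrays at position 4. Correlations of log2 changes were set against simulated unchanged groups in 100 draws, overlaps of called probes against independent lists, and counts against 100 splits of the arrays. Scores used the 500 probes with the smallest p in a comparison, chosen without the array scored, and were centred on the 60 arrays outside both groups. The centring was added after the scores without it had been seen. For CUST_21187_PI417904088, all 48 arrangements of the group means within the mixture experiment and within the pLD pair were compared by the slope over the levels plus the pLD difference (an exact, one-sided permutation test with groups as units).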

Results

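RNA from the olfactory rosettes of juvenile coho salmon (Oncorhynchus kisutch), the paired sensory organs of the nose, was measured on 70 one-colour arrays with 43689 probes each. Fish had been exposed for 24 h, in aquaria holding 70 L of water and 8 fish at 11 °C, to chlorpyrifos, to malathion, to a mixture of both, or to the carrier alone. Chlorpyrifos and malathion are organophosphate insecticides that inhibit acetylcholinesterase. The arrays fell into 14 groups of 5. Each of the chlorpyrifos, malathion and mixture experiments had its own control group and 3 exposure levels labelled Low, Medium and High, and a separate pair of groups was labelled Mix pLD Control and Mix pLD. The labels used here gave no concentrations and did not explain pLD. The files do not pair the probes with gene names, so probes are given below by their identifiers and 60-base sequences, and no pathway or cell type could be described.

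The 75th percentile of processed signal ran from 92.5 to 500.2 between arrays, with a median of 298, and 52.5% to 81.2% of probes on an array were well above background. Signal levels below are log2 values relative to the array's own 75th percentile, and 33354 probes were tested. A probe is called changed where limma's adjusted p (Benjamini-Hochberg) was under 0.05. No label said that the 5 fish of a group came from separate aquaria, so a difference between groups could also be one between tanks. In the main fit the p-values measure the spread between fish within groups, pooled over all 14 groups, not that of the compared groups alone. The number of arrays, 5 per group, limits the precision of every value.

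A few probes were much higher in Chlorpyrifos High than in its controls. The clearest was CUST_21187_PI417904088 (identifier 12_4_18_22, sequence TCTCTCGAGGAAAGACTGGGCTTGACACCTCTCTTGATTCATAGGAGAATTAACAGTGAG), which rose from 0.21 ± 0.33 in the controls to 2.63 ± 0.22 in Chlorpyrifos High (SD, n = 5 each). That is a 5.34-fold rise (log2 2.42 ± 0.27 SE, limma adjusted p = 5.90e-08), and all 5 exposed fish were above the control mean. Its mean was 0.97 ± 0.83 at the Low level and 1.36 ± 0.17 at the Medium level (SD, n = 5 each). Neither was past the threshold alone, with adjusted p = 1.00 and 0.295, while the trend over the levels was (adjusted p = 6.03e-08). CUST_39901_PI417904088 (sequence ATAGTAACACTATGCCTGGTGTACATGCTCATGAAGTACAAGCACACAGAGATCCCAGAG) rose 5.57-fold at the High level (log2 2.48 ± 0.31 SE, adjusted p = 1.37e-06), but was not called with normexp background correction (1.01) or with slide and array position fitted together (2.72, adjusted p = 0.112).

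In all, 5 probes were called in Chlorpyrifos High, 4 higher and 1 lower. The other higher probes rose 3.44-fold (adjusted p = 0.00391) and 2.18-fold (adjusted p = 0.0106). The lower one, CUST_12548_PI417904088 (sequence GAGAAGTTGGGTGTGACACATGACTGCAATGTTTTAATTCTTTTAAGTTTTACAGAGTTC), fell 2.09-fold (log2 -1.06 ± 0.19 SE, adjusted p = 0.00690). It was below the control in 4 of the 5 slides that held both groups and higher by 0.49 in the remaining one. Its call was lost in 9 of 32 alternative settings, among them those without Chlorpyrifos High replicate 4 (adjusted p = 0.112) or replicate 8 (adjusted p = 0.0731). Within those 5 slides, each scanned on its own day, CUST_21187_PI417904088 was higher in all 5, by 2.24 to 2.71 on the log2 scale, and CUST_39901_PI417904088 by 2.12 to 2.84. The Chlorpyrifos High arrays all sat at position 1 of their slides and the Chlorpyrifos Control arrays all at position 4. With array position as a covariate, which other experiments inform, the count was 2 (and 1 with normexp correction), the first of these probes differed by 2.48 (adjusted p = 9.02e-05) and the second by 2.83 (adjusted p = 9.02e-05). The count was 10 with the slide and 6 with the scan day as a block, 159 without Chlorpyrifos High replicate 2, 8 without replicate 5 and 3 without replicate 8. Of the 5 calls 80.0% were higher, against 55.6% of 9 calls in the authors' deposited table.

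At the Medium level of chlorpyrifos 1 probe was called. CUST_26736_PI417904088 (sequence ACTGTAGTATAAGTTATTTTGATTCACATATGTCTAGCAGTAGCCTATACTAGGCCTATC) was well above background on all 5 control arrays and on 0 of 5 Chlorpyrifos Medium arrays, and was at least 3.90-fold lower (adjusted p = 0.0190), with all 5 shared slides showing that direction. It was also well above background on 0 of 5 Chlorpyrifos High arrays, where it was at least 2.65-fold lower but missed the threshold (adjusted p = 0.0521), which it passed in 9 of 31 alternative settings. In the other control groups it was well above background on 0 (Malathion Control), 2 (Mixture Control) and 5 arrays (Mix pLD Control), with means of -4.88, -4.12 and -2.49 against -2.90 in Chlorpyrifos Control. A bound sets the bright group's mean against the lowest signal counted as well above background on each array of the dim group, or the probe's own signal where that was higher. The Medium call was lost without Chlorpyrifos Control replicate 3, 4, 5 or 6 and without Chlorpyrifos Medium replicate 6, 7 or 8, each of which left 0 called probes, and 4 were called without Chlorpyrifos Medium replicate 2. It was also lost with array position as a covariate (adjusted p = 0.453), and the count was 2 with the slide as a block and 0 with normexp correction. At the Low level limma called 0 probes, with 512 at an unadjusted p under 0.05, where chance gives 1668, and 0 with the slide as a block. Over all levels 9 probes followed a chlorpyrifos trend, 7 upwards and 2 downwards, with 2 when position was a covariate, 1 with slide and position together, 1 with normexp correction and 13 when the slide was a block; 77.8% were upwards, against 62.5% in the authors' deposited table.

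**Figure D1:**
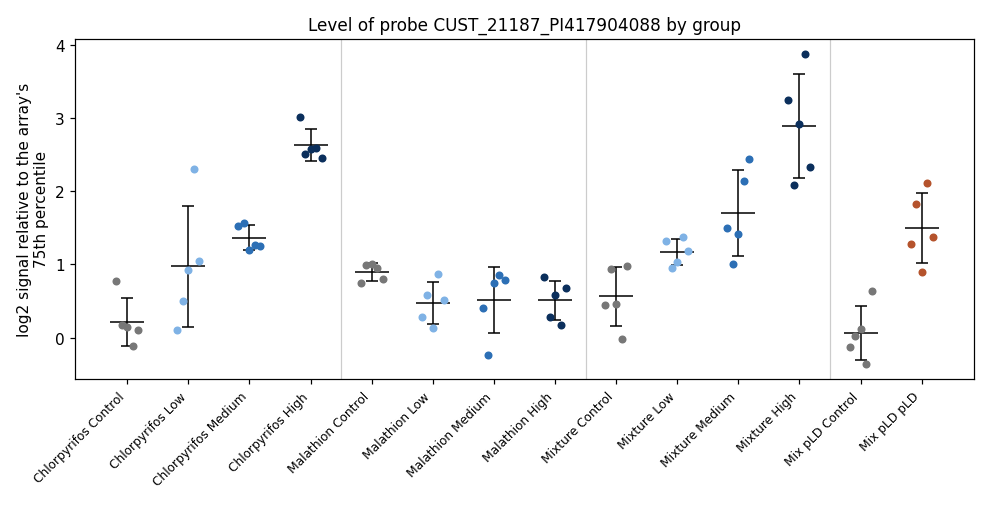
Level of probe CUST_21187_PI417904088 in each of the 14 groups, as log2 signal relative to the array's 75th percentile. Points are the 5 arrays of a group, the long bar is their mean and the whiskers are 1 SD; means reach 2.63 in Chlorpyrifos High and 2.89 in Mixture High and lie between 0.47 and 0.90 in the 4 malathion groups.

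Many probes differed between the malathion groups at the Medium and High levels and Malathion Control. In Malathion Medium 4404 probes were called, 2850 higher and 1554 lower than in Malathion Control, with a median change of 1.61-fold, and 895 differed by over 2-fold. In Malathion High 4317 were called, 2279 higher and 2038 lower, with 871 over 2-fold. The 2 lists shared 1266 probes higher in both and 1147 lower in both, with 0 in opposite directions, where independent lists would share 194.7 and 94.95. Both lists rest on the same 5 control arrays. Across probes the log2 changes correlated at r = 0.723 (covariance 0.155), against a mean of 0.499 and an upper limit of 0.706 (mean covariance 0.0473) for 95% of simulated unchanged groups with shared controls. When the controls were split between the lists the observed value was 0.432 (covariance 0.112), against -0.274 to 0.308 for simulated unchanged groups with separate controls. Those limits are only a rough guide, since the split subsets held fewer arrays than the 5 of a simulated control group. The observed value was also a mean over all splits, and the simulation drew arrays of any group regardless of slide.

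Among Malathion Medium probes, CUST_308_PI417904088 (identifier 1_1_15_5, sequence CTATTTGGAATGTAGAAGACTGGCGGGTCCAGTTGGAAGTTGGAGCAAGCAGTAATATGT) fell 5.18-fold (log2 -2.37 ± 0.43 SE, adjusted p = 0.000172) and was lower on all 4 slides that held both groups. Its mean was 0.04 in Malathion Medium and 2.42 in Malathion Control, and 2.31, -0.24 and -1.04 in the Mix pLD, Chlorpyrifos and Mixture Controls. It also fell 4.87-fold in Malathion Low (adjusted p = 0.0197), where that call was lost without Malathion Control replicate 3, 4 or 6 or Malathion Low replicate 2 or 8, with adjusted p of 0.0550, 0.0558, 0.0875, 0.0975 and 0.173. In Malathion High it stood at -0.79 (adjusted p = 0.215). CUST_30432_PI417904088 (sequence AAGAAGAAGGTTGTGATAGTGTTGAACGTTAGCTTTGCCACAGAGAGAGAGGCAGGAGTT) was at least 4.45-fold higher in Malathion Medium (adjusted p = 0.0257) and well above background on 5 of 5 exposed and 1 of 5 control arrays. It was higher on all 4 shared slides, and its call was lost in 11 of 31 alternative settings. These include the fits without Malathion Control replicate 6 or Malathion Medium replicate 2 or 7 (adjusted p = 0.0555, 0.0503 and 0.0556). CUST_3248_PI417904088 (sequence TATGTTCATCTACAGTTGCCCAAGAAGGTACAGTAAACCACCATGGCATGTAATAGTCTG) was at least 5.08-fold higher (adjusted p = 0.0362), was well above background on 3 of 5 control arrays, and lost its call in 18 of 31 alternative settings. Among these were the fits without Malathion Control replicate 2, 6 or 7 or Malathion Medium replicate 2, 3, 4 or 5 (adjusted p from 0.0568 to 0.125) and with the slide as a block (adjusted p = 0.0970). CUST_8335_PI417904088 (sequence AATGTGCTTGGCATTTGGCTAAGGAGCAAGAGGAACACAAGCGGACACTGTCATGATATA) fell by 1.74 ± 0.50 SE on the log2 scale (adjusted p = 0.0153), with 4 of 5 exposed arrays well above background and an SD of 2.06 among the 5, and was not called without Malathion Medium replicate 5 (-0.83, adjusted p = 0.128) or Malathion Control replicate 4 (-1.24, adjusted p = 0.120).

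In Malathion High, CUST_32457_PI417904088 (sequence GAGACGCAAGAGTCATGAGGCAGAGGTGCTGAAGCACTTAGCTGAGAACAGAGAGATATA) fell 13.8-fold (log2 -3.79 ± 0.72 SE, adjusted p = 0.000354), from 5.15 ± 0.19 in the controls to 1.36 ± 4.08 in the exposed fish (SD, n = 5 each). Of these, 2 fish were at -3.50 and -2.66 and the other 3 between 3.80 and 4.59. The SE and adjusted p rest on the spread pooled over all 14 groups, so they do not show this split of the exposed fish. The change was -2.58 without Malathion High replicate 1, -2.78 without replicate 2, and -4.59, -4.40 and -4.60 without replicates 4, 5 and 6. CUST_27598_PI417904088 (sequence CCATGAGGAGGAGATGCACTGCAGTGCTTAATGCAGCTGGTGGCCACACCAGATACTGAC) fell 8.67-fold (log2 -3.12, adjusted p = 0.000523), with the same 2 fish at -2.98 and -1.65 and the other 3 between 3.94 and 4.55 (SD 3.64). Its change was -1.96 and -2.29 without replicates 1 and 2, and -3.79 and -3.84 without replicates 4 and 6. The pooled spread also lies behind its adjusted p and that of the next probe, whose exposed fish had an SD of 2.76. CUST_3227_PI417904088 (sequence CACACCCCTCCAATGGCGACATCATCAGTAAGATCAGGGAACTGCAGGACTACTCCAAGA) was at least 4.46-fold higher (measured log2 difference 2.90, adjusted p = 0.00731), with a measured difference of 1.68 without Malathion High replicate 2 (adjusted p = 0.0645). CUST_32007_PI417904088 (sequence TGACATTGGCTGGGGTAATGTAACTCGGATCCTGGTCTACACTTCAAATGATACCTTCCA) was at least 2.79-fold higher (adjusted p = 0.000808). The last 2 were well above background on 5 of 5 exposed and 2 of 5 control arrays each. The calls of these probes were lost in 6 of 31, 6 of 31, 8 of 30 and 4 of 30 alternative settings. All 4 probes kept their direction on each of the 3 scan days shared with the controls, with differences from -7.70 to -1.25, -6.29 to -0.92, 1.65 to 8.12 and 1.80 to 3.36 in the order given.

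Malathion High and Malathion Control shared 0 slides, and with the slide as a block Malathion High had 605 called probes, with 4183 for the scan day as a block, and the first 2 of its named probes stood at -0.26 each (adjusted p = 0.988 and 0.987). Over the 4317 called probes the slide block moved the median change in the called direction from 0.67 to 0.53 (log2) and the median SE from 0.18 to 0.36. It kept 240 of these calls, with 93.3% of the probes in the same direction. Malathion Medium shared 4 slides with its controls and had 4436 called probes with that block, 2620 with array position as a covariate and 1263 with both, where Malathion High had 393. The Malathion High count was 2208 without Malathion High replicate 5 and 2427 in a fit of the malathion arrays alone. The share of higher calls depended on scaling: 64.7% in Malathion Medium against 40.2% after median scaling, 50.1% after quantile normalization and 47.3% in the authors' deposited table, and 52.8% in Malathion High against 33.8%, 36.2% and 38.1%. With normexp background correction the counts were 61 and 22, of which 52.5% and 9.09% were higher.

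At the Low level of malathion 4 probes were called, 2 lower and 2 higher. The authors' deposited table also gave 4 calls, of which 0% were higher, and quantile normalization gave 6, of which 66.7% were higher. Besides CUST_308_PI417904088, CUST_38851_PI417904088 (sequence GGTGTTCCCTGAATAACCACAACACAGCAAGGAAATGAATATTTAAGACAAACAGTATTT) fell 2.91-fold (adjusted p = 0.0364), a call lost in 17 of 32 alternative settings, among them the slide as a block (adjusted p = 0.110). They include the fits without Malathion Control replicate 2, 4 or 6 or Malathion Low replicate 1, 2, 3 or 8 (adjusted p from 0.0610 to 0.203). Named after their values were seen, probe 9_4_16_4 (sequence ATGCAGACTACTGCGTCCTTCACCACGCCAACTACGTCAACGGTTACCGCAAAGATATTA) was at least 1.25-fold higher (adjusted p = 0.00166) and CUST_29559_PI417904088 (sequence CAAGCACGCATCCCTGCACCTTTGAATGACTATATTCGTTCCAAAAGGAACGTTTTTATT) at least 1.02-fold higher (adjusted p = 0.00166). These were well above background on 4 and 3 of 5 exposed arrays and on 1 of 5 control arrays each, so the sizes are bounds, and with normexp correction the first stood at -0.05. Their Malathion Control means, -4.70 and -5.03, were the lowest of the 4 control groups, the others lying between -3.82 and -3.36. Naming probes by their rise over Malathion Control favours that. CUST_29559_PI417904088 was not called without Malathion Control replicate 6 (adjusted p = 0.0668). The count was 9 without Malathion Control replicate 3, 1 without Malathion Control replicate 6 and 10 without Malathion Low replicate 5, and 4 with the slide as a block. It was 2 with array position as a covariate and 0 with normexp correction, in a fit of the malathion arrays alone or on shared slides. The trend over malathion levels called 7908 probes, 4513 upwards and 3395 downwards, with 809 when the slide was a block and 442 with normexp correction. Of the 7908, 57.1% were upwards, against 39.6% after median scaling and 41.5% after quantile normalization.

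**Figure D2:**
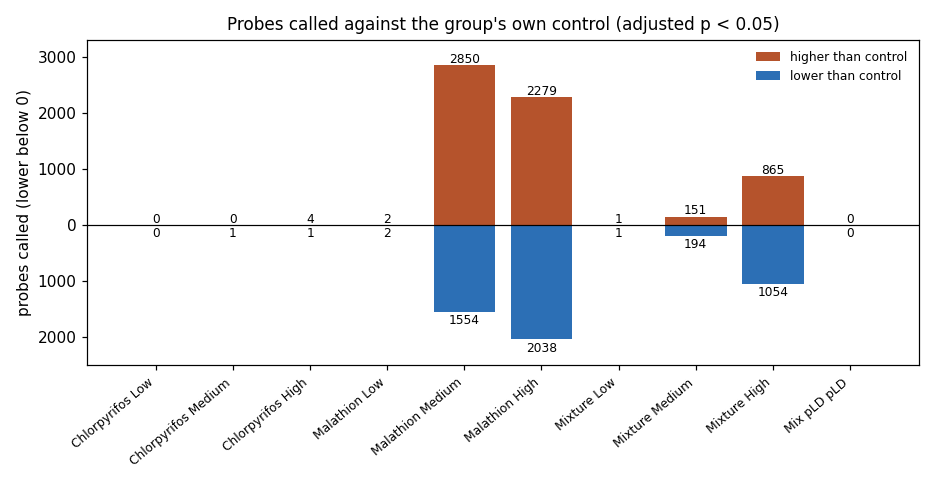
Number of probes called against the group's own control at each exposure level, with probes higher than the control drawn above 0 and probes lower drawn below 0. Malathion Medium has 2850 higher and 1554 lower probes, Malathion High 2279 and 2038, Mixture High 865 and 1054, and each chlorpyrifos level 5 or fewer in all.

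The probe that led in Chlorpyrifos High was also higher in the mixture groups. CUST_21187_PI417904088 went from 0.56 ± 0.41 in Mixture Control to 1.17 ± 0.18, 1.70 ± 0.58 and 2.89 ± 0.71 at the Low, Medium and High levels (SD, n = 5 each). The rise was 5.03-fold in Mixture High (log2 2.33 ± 0.27 SE, adjusted p = 1.98e-07) and 2.20-fold in Mixture Medium (adjusted p = 0.0250), while the Mixture Low difference of 0.61 was short of the threshold (adjusted p = 1.00). It was higher on both slides that held Mixture High and Mixture Control, by 1.63 and 2.31, and a fit of those slides alone gave 1.97 (adjusted p = 0.215). CUST_39901_PI417904088 rose 4.50-fold in Mixture High (adjusted p = 1.78e-05), with 4 of 5 control arrays well above background. All 4 probes called higher in Chlorpyrifos High were called higher in Mixture High, where independent lists would share 0.104. CUST_12548_PI417904088 differed from Mixture Control by 1.19 in Mixture High (adjusted p = 0.000147), but its control groups were at different levels. It stood at 1.37 in Mixture High, 0.18 in Mixture Control, 0.18 in Mix pLD Control, 1.36 in Chlorpyrifos Control and 1.42 in Malathion Control.

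Mixture High had 1919 called probes, 865 higher and 1054 lower, with 501 over 2-fold. CUST_11212_PI417904088 (identifier 7_1_14_12, sequence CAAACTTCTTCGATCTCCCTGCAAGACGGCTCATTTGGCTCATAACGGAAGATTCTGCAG) rose 5.36-fold (log2 2.42 ± 0.48 SE, adjusted p = 0.00171), with differences of 0.58 to 4.93 on the 3 shared scan days, and lost its call in 6 of 32 alternative settings. CUST_35618_PI417904088 (sequence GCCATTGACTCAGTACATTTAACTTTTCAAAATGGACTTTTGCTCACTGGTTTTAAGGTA) and CUST_19635_PI417904088 (identifier 12_1_4_4, sequence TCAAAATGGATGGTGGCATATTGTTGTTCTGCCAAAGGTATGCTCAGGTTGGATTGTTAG) were well above background on 5 of 5 control arrays and 0 of 5 Mixture High arrays. They were at least 1.86-fold (adjusted p = 0.0119) and at least 2.11-fold lower (adjusted p = 0.000361), and lost their calls in 10 and 5 of 31 alternative settings, which for the first include the fit without Mixture Control replicate 1 (log2 -1.68). Their Mixture Control means of -2.35 and -2.16 were the highest of the 4 control groups, the others lying between -5.00 and -3.59. Naming probes by their fall from Mixture Control favours that. In all, 101 called probes were well above background on every Mixture Control array and on no Mixture High array, with 58.9% ± 5.68 of all probes well above background in Mixture High and 72.4% ± 4.94 in Mixture Control (SD, n = 5 each). The Mixture High count was 711 without Mixture Control replicate 1, 64.3% of its size without Mixture Control replicate 3, and 4932 with the slide as a block. It was 3510 with the scan day as a block and 688 with array position as a covariate. On the slides holding both groups it was 0, and with normexp correction 1. It was 16 in a fit of the mixture arrays alone, which had fewer arrays and used only their own spread. The 1919 calls rest on the spread pooled over all 14 groups. Of them 45.1% were higher, against 32.7% of those in the authors' deposited table.

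Mixture Medium had 345 called probes, 151 higher and 194 lower. Of these, 95 were higher and 109 lower in Mixture High too, with 0 in opposite directions, where independent lists would share 3.92 and 6.13. Both lists rest on the same 5 Mixture Control arrays. The correlation across probes was r = 0.615 (covariance 0.0977), and 95% of simulated unchanged groups with shared controls lay between 0.250 and 0.706 (mean 0.499, mean covariance 0.0473). With split controls it was 0.235 (covariance 0.0474), against -0.274 to 0.308 for simulated groups with separate controls. Both correlations were within the range of unchanged groups, while the covariances were above the upper limits of 0.0904 and 0.0271 of the same simulations. For the split controls these limits are only a rough guide, since the split subsets held fewer arrays than the 5 of a simulated control group. The simulation also drew arrays of any group, not of the mixture experiment alone. CUST_19635_PI417904088 was lower in Mixture Medium (measured log2 difference -2.11, adjusted p = 0.00297) and at least 3.85-fold lower in Mixture Low (adjusted p = 0.0286), with 2 and 3 of 5 exposed arrays well above background. CUST_35618_PI417904088 was at least 2.86-fold lower in Mixture Medium (adjusted p = 0.0387), with 3 of 5 exposed arrays well above background, and lost that call in 16 of 31 alternative settings, including those without Mixture Control replicate 1, 2, 3 or 4 or Mixture Medium replicate 2 or 6 (adjusted p from 0.0510 to 0.164). CUST_20250_PI417904088 (sequence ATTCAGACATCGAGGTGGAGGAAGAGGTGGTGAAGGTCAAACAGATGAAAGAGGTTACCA) was at least 2.29-fold higher (adjusted p = 0.0253) and CUST_13460_PI417904088 (sequence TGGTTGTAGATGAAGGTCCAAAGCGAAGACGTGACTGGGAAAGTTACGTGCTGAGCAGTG) at least 1.79-fold higher (adjusted p = 0.0460), with 1 and 3 of 5 control arrays well above background. Both reversed with normexp correction, to log2 differences of -0.56 and -0.57. The first was not called without Mixture Control replicate 3 or 4 or Mixture Medium replicate 4, 5 or 6 (adjusted p from 0.0526 to 0.130), and the second without Mixture Control replicate 1, 2, 3 or 4 or Mixture Medium replicate 2, 4, 5 or 6 (adjusted p from 0.0538 to 0.223). The count was 113, 604, 80, 47 and 807 without Mixture Control replicates 1 to 5 in turn, 157, 149 and 159 without Mixture Medium replicates 2, 4 and 5, and 1709 with the slide and 1412 with the scan day as a block. It was 74 with array position as a covariate, 4 with slide and position together and 7 on the slides holding both groups. In a fit of the mixture arrays alone, which used only their own spread, it was 0, and with normexp correction it was 16. The share of higher calls was 43.8%, against 54.2% after quantile normalization.

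In Mixture Low 2 probes were called. CUST_19635_PI417904088 was the lower one, and its call there was lost in 15 of 31 alternative settings, including those without Mixture Control replicate 2, 3 or 4 or Mixture Low replicate 1, 3, 4 or 6 (adjusted p from 0.0758 to 0.583). The higher one, CUST_36347_PI417904088 (sequence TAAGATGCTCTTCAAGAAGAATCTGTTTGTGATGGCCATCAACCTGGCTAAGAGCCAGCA), named after its values were seen, was well above background on 3 of 5 exposed and 0 of 5 control arrays and was at least 1.14-fold higher (adjusted p = 0.0210). Its mean was -5.64 in Mixture Control, between -4.09 and -3.85 in the other 3 control groups and -4.09 in Mixture Low. Its difference was -0.85 with normexp correction, and it was not called without Mixture Control replicate 1, 3 or 4 or Mixture Low replicate 1, 3 or 6 (adjusted p from 0.0694 to 0.135). Both probes kept their direction on all 5 slides that held both groups, and the count was 4 with the slide as a block and 0 with normexp correction, on shared slides or in a fit of the mixture arrays alone. Leaving out an array moved the count to 0 (Mixture Control replicate 3 or 4, Mixture Low replicate 1, 3 or 6), 1 (Mixture Control replicate 1, Mixture Low replicate 4), 6 (Mixture Control replicate 5), 8 (Mixture Control replicate 2) or 9 (Mixture Low replicate 2). The trend over mixture levels called 3164 probes, 1364 upwards and 1800 downwards, or 43.1% upwards against 32.8% in the authors' deposited table, and 6108 with the slide as a block. That trend count was 1203 with array position as a covariate, 159 in a fit of the mixture arrays alone and 2 with normexp correction.

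In the Mix pLD pair limma called 0 probes at the adjusted threshold, with 1329 at an unadjusted p under 0.05. The smallest adjusted p, 0.0622, belonged to CUST_21187_PI417904088, which was 1.49 ± 0.48 in Mix pLD and 0.06 ± 0.37 in its controls (SD, n = 5 each), a difference of 1.44 ± 0.27 SE. It was higher on all 4 slides that held both groups, by 0.77 to 1.86, and passed the threshold with the slide as a block (1.54, adjusted p = 0.00387). The count was 27 with that block and 1 without Mix pLD Control replicate 8 or Mix pLD replicate 4, where this probe's adjusted p was 0.0247 and 0.0217.

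The changes with the 2 compounds, each against its own control group, were compared directly. Chlorpyrifos Control and Malathion Control themselves differed at 2514 probes, so a difference between changes can also be one between these controls. CUST_21187_PI417904088 changed by 1.53 ± 0.38 SE more on the log2 scale in chlorpyrifos than in malathion at the Medium level (adjusted p = 0.00801) and by 2.80 ± 0.38 SE more at the High level (adjusted p = 2.89e-05). Its level was 0.21 in Chlorpyrifos Control and 0.90 in Malathion Control. In the malathion groups it stood at -0.42, -0.38 and -0.39 from the control at the Low, Medium and High levels (adjusted p = 0.799, 0.354 and 0.355). CUST_39901_PI417904088 differed by 2.36 ± 0.44 SE at the High level (adjusted p = 0.00669). The chlorpyrifos change minus the malathion change passed the threshold for 0 probes at the Low level (1259 at an unadjusted p under 0.05), 2750 at the Medium level, 842 higher and 1908 lower, and 108 at the High level, 38 higher and 70 lower. Higher differences made up 30.6% at the Medium level against 57.3% after median scaling and 41.4% after quantile normalization, and 35.2% at the High level against 50% and 65.7%. With the slide as a block the counts were 0, 3230 and 416, with position as a covariate 31 at the High level, and with normexp correction 35 at Medium and 1 at High. The labels do not say how the levels of the 2 compounds compare.

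The mixture's change was also set against the sum of the changes with each compound at the level of the same name. For CUST_21187_PI417904088 the difference from the sum was 0.30 ± 0.47 SE at the High level (adjusted p = 0.712). CUST_12548_PI417904088, which fell with each compound at the High level, by 1.06 with chlorpyrifos and by 1.42 with malathion (adjusted p = 4.09e-06), was 3.67 ± 0.33 SE above the sum (adjusted p = 1.07e-11), with the control levels given above: 0.18 in Mixture Control against 1.36 and 1.42. In all, 0 probes departed from the sum at the Low level (1098 at an unadjusted p under 0.05), 555 at the Medium level, 290 above and 265 below, and 5018 at the High level, 2487 above and 2531 below. At the Medium level 52.3% were above, against 66.2% after median scaling and 65.4% after quantile normalization, and at the High level 49.6% against 62.5% after median scaling. With the slide as a block the counts were 0, 1048 and 2529, with slide and position together 1559 at the High level, and with normexp correction 9 at Medium and 172 at High. Of the probes called in both Malathion High and Mixture High, 643 moved in opposite directions, 10 were higher in both and 1 was lower in both, where independent lists would give 124.9, 59.1 and 64.4. The correlation across probes was r = -0.318, where 95% of simulated unchanged groups with separate controls lay between -0.274 and 0.308. The 2 control groups behind these lists differed from each other at 8078 probes. On a score from the 500 probes with the smallest p in Mixture High, Malathion Control stood at 0.29 ± 0.06 and Mixture Control at -0.29 ± 0.18, with Mixture High at 0.21 ± 0.15 and Malathion High at -0.15 ± 0.06 (SD, n = 5 each). These comparisons therefore do not separate a difference between exposures from one between the control groups.

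The 4 control groups differed among themselves at 9714 probes, at 1350 with the slide as a block and at 348 with normexp correction. Malathion Control was the most distant, with 8078 probes differing from Mixture Control, 7121 from Mix pLD Control and 2514 from Chlorpyrifos Control, against 446 to 1356 among the other pairs. A score was formed from the 500 probes with the smallest p in Malathion Medium against Malathion Control, each array scored on probes chosen without it. On this score Malathion Control was -0.37 ± 0.12, Malathion Low -0.38 ± 0.07, Malathion Medium 0.33 ± 0.09 and Malathion High 0.23 ± 0.06 (SD, n = 5 each). Malathion Control had the lowest mean of the 4 control groups for CUST_30432_PI417904088, CUST_3248_PI417904088, CUST_3227_PI417904088 and CUST_32007_PI417904088, dim probes higher in Malathion Medium or High. They were picked as higher than Malathion Control, which favours a low mean there, so this adds nothing to the score. On the score the other control groups had positive means of 0.07 ± 0.09 (Chlorpyrifos Control), 0.13 ± 0.13 (Mixture Control) and 0.25 ± 0.07 (Mix pLD Control).

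**Figure D3:**
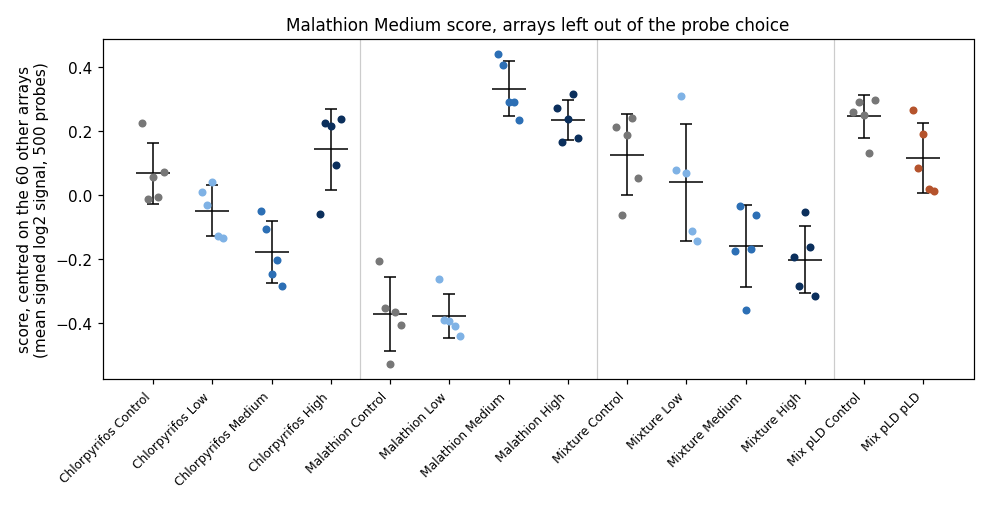
Score of every array over 500 probes chosen from Malathion Medium against Malathion Control without the array scored, as mean log2 signal signed by the direction of change and centred on the 60 arrays outside those groups. Points are arrays, long bars are group means and whiskers are 1 SD; Malathion Control and Malathion Low have means of -0.37 and -0.38, and the other 3 control groups have means from 0.07 to 0.25.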

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

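The tests of array position and slides for the malathion counts, of dim arrays, of brightness, of the share of probes well above background, of slides holding both groups, of whether Malathion Control stands apart and of tanks, and all splits of the arrays, were chosen after the data were seen; the tests of position for Mixture High and of the malathion response in the mixture were written before their values were seen.

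Malathion Medium and Malathion High differed from Malathion Control at 4404 and 4317 probes. A position effect is argued against as the whole cause, since Chlorpyrifos High against its controls, positions 1 and 4 throughout, showed 10.68% of the Malathion Medium score. For Malathion Medium part of it stays open. Position as a covariate gave 2620 calls, 2263 of them among the 4404. Slide and position together gave 1263, 1101 of them among the 4404. Over the 4404 the median change was then 0.59 against 0.69, with a larger median SE (0.23 against 0.19). For Malathion High, position as a covariate kept 3910 of the 4317 calls, with a median change of 0.67 and a median SE of 0.18 with or without it. These values argue against a position effect that is linear along the slide there. Slide and position together gave 393 Malathion High calls, 137 of them among the 4317. The slide alone gave 605, 240 of them among the 4317. None of the 3 dim arrays (75th percentile under 149) was in Malathion Medium or Malathion Control, where the lowest values were 211 and 223. The 5695 Malathion Medium calls without them are therefore no test of dim arrays, since only the pooled spread changed. The dim arrays stay open for Malathion High (2688 calls), whose replicate 5 was at 127. The share of probes well above background is argued against with 4938 and 4936 calls when it was a covariate. Slides are argued against for Malathion Medium, with 4808 calls on the slides holding both groups. They stay open for Malathion High, which shared 0 slides with its controls. The slide as a block kept 240 of its 4317 calls, with 93.3% of the 4317 probes in the same direction. Precision was lower, as the median SE went from 0.18 to 0.36 and the median change only from 0.67 to 0.53. With the scan day as a block 4183 probes were called, 3719 of them among the 4317. A score from Malathion High's own probes, chosen without the arrays scored, was higher by 0.45 to 0.86 on all 3 shared scan days. The Malathion Control arrays themselves may also stand apart, as the other 3 control groups lay 73.58% of the way from Malathion Control to Malathion Medium on the score, although probes picked for that difference can place any other group between those 2; a response to malathion stays open too.

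Mixture High differed from Mixture Control at 1919 probes. The dim array Mixture High replicate 3 is argued against as the cause, with 1857 calls without it alone. The 2525 calls without all dim arrays also reflect a changed pooled spread, since the others were Malathion High replicate 5 and Mix pLD Control replicate 7. With brightness as a covariate 3856 probes were called, which argues only against an effect linear in log2 brightness. Mixture High was dimmer than Mixture Control as a whole (mean 75th percentile 219 against 326). A malathion-like response is argued against, since the Malathion Medium score moved the other way, to -46.71% of its size. This holds as far as that score stands for malathion rather than for Malathion Control. The share of probes well above background stays open, since with it as a covariate 1209 probes were called. Position could also contribute. The 2 Mixture High arrays at position 4 reached 113.3% of the score of the other 3. This met the bound set beforehand against this cause. That bound was too weak, because the value was 14.27% without centring and rests on 2 arrays, and position as a covariate gave 688 calls. A response to the mixture is among the open explanations and was not tested apart from these.

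CUST_21187_PI417904088 was higher in Chlorpyrifos High and Mixture High and not called in any malathion group. A hypothesis is that it follows chlorpyrifos exposure, alone or in the mixture. Tank differences stay open, as the labels do not say which fish shared a tank. The group means rose with the level in the mixture experiment and pLD was above its control. The real order was thus the only 1 of the 48 arrangements of these means (2.08%, the smallest share possible) to follow the levels so closely. That test cannot decide about tanks, because it was chosen after these means had been seen. It also took pLD as the higher exposure, which the labels do not explain, and the probe was among those picked in Mixture High and the pLD pair. Its change in Chlorpyrifos High was past the threshold with the slide as a block (2.42), with position as a covariate (2.48) and with both (2.64), and with the slide as a block its change in Mixture High was 2.51. The call in Mixture High was kept in 31 of 32 alternatives, and lost where only the slides holding both groups were used (1.97, adjusted p = 0.215).

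Single fish stood far from the rest of their group for 8 of the 86 groups of 5 values examined, where chance gives about 5%. Chlorpyrifos High replicate 2 did so 3 times: at 3.01 for CUST_21187_PI417904088 (other fish 2.45 to 2.59), at -0.24 for CUST_39901_PI417904088 (others -1.08 to -0.84) and at 1.48 for CUST_12548_PI417904088 (others -0.18 to 0.22). Malathion Control replicate 6 was at -6.07 for CUST_30432_PI417904088 (others -5.12 to -4.94), and Malathion Control replicate 4 at -0.21 for CUST_8335_PI417904088 (others -2.44 to -2.08). Malathion Medium replicate 5 was at -7.09 for the same probe (others -3.02 to -2.03), Malathion High replicate 2 at 3.69 for CUST_3227_PI417904088 (others -2.91 to -2.09), and Mixture Medium replicate 6 at -1.52 for CUST_13460_PI417904088 (others -3.23 to -3.04). Tests of differences between changes passed for 2750 probes (chlorpyrifos against malathion, Medium), 108 (the same, High), 555 (mixture against the sum, Medium) and 5018 (the same, High).

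Counts were set against 100 splits of the same arrays, the real one included. The bound against chance was that fewer than 5 splits called as many probes. The splits treat the fish as exchangeable, which fails if the fish of a group shared a tank. They also ignored slides, and 20 counts were compared without correction. The bound was met in Malathion Medium (1 of 100 splits, 4404 called, at most 427 in another split), Malathion High (1 split, 4317 called, at most 951) and Mixture High (3 splits, 1919 called, at most 2720). Chlorpyrifos Medium (1 split, 1 probe called, at most 0) and Malathion Low (3 splits, 4 called, at most 14) also met it. Their small counts do not exclude chance, as 8 and 3 of the 10 fits without 1 array moved them over 1.5 times. The bound was not met in Chlorpyrifos High (5 splits, 5 called, at most 89), Mixture Low (13 splits, 2 called, at most 1284) or Mixture Medium (6 splits, 345 called, at most 1348). After removal of the group means, arrays of different groups on the same slide correlated on average at 0.168 (chlorpyrifos), 0.148 (pLD), 0.114 (malathion) and 0.050 (mixture). On other slides the means were -0.036, -0.048, -0.014 and -0.007. A split uneven over slides therefore also holds slide differences. The same-slide value was lowest in the mixture experiment, where single splits called up to 2720 probes. In Chlorpyrifos High, Malathion Low, Mixture Low and Mixture Medium some splits called several times the real count, and in Mixture High some called more than the real one, which points to a structure of the samples. The bound was also met for the chlorpyrifos trend (1 split, 9 called, at most 1), the malathion trend (1 split, 7908 called, at most 728), the mixture trend (1 split, 3164 called, at most 2522) and the control groups (1 split, 9714 called, at most 1270). For the chlorpyrifos and malathion difference it was met at Medium (1 split, 2750 called, at most 2248) and High (1 split, 108 called, at most 37). For the departure from the sum it was met at Medium (4 splits, 555 called, at most 950, more than the real one) and High (1 split, 5018 called, at most 279). These splits shuffled the labels within every experiment, so a change in 1 experiment alone can exceed them. They therefore do not decide whether the changes differed from each other or from the sum. Where 0 probes were called, all 100 splits call as many by construction, so the splits decide nothing: this holds for Chlorpyrifos Low (at most 0 in another split), the pLD pair (at most 4) and both of these differences at Low (at most 2).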

How the results depend on the processing

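Fits without the 3 dim arrays, with brightness or the share of probes well above background as a covariate, on shared slides only, and 2 of the normexp settings were chosen after the results were seen. Across 16 alternatives set beforehand and 6 added, counts of called probes stayed within 1.5 times in 250 cases and moved further in 177. Named probes gave 906 values: 648 kept their direction and side of the threshold, 232 were no longer past it, 19 came past it and 7 reversed. CUST_308_PI417904088 in Malathion Medium passed in all 32 of its alternative fits. The cause was not tested for any moved value below unless given. Dim signal limits the calls, as 10335 probes were too dim to test.

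With normexp correction (offset 50), probe 9_4_16_4 in Malathion Low reversed to -0.050, CUST_13460_PI417904088 and CUST_20250_PI417904088 in Mixture Medium to -0.57 and -0.56, and CUST_36347_PI417904088 in Mixture Low to -0.85. It called 1 probe in Chlorpyrifos High, 0 in Chlorpyrifos Medium, 22 in Malathion High, 0 in Malathion Low, 61 in Malathion Medium, 1 in Mixture High, 0 in Mixture Low and 16 in Mixture Medium. Departures from the sum were 172 (High) and 9 (Medium), differences among controls 348, chlorpyrifos against malathion 1 (High) and 35 (Medium), and trends 1 (chlorpyrifos), 442 (malathion) and 2 (mixture). With normexp and no offset, the last 3 of these probes stood at -0.77, -0.75 and -1.20. It called 1 in Chlorpyrifos High, 0 in Chlorpyrifos Medium, 14 in Malathion High, 0 in Malathion Low, 53 in Malathion Medium, 2 in Mixture High, 0 in Mixture Low and 6 in Mixture Medium. Departures were 167 (High) and 3 (Medium), controls 163, chlorpyrifos against malathion 1 (High) and 25 (Medium), and trends 1, 383 and 2. With normexp and quantile normalization the counts were 10 in Chlorpyrifos High, 0 in Chlorpyrifos Medium, 2773 in Malathion High, 1930 in Malathion Medium, 1 in the pLD pair, 2928 in Mixture High, 0 in Mixture Low, 5888 for controls and 41 (High) and 1052 (Medium) for chlorpyrifos against malathion.

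In the authors' deposited table the counts were 9 in Chlorpyrifos High, 0 in Chlorpyrifos Medium, 2314 in Malathion Medium, 2 in the pLD pair, 1 in Mixture Low, 187 in Mixture Medium, 1 (Low) and 347 (Medium) for departures from the sum, and 59 (High) and 1294 (Medium) for chlorpyrifos against malathion. It gave 18531 for the controls; whether its experiments were normalized together is not known. Quantile normalization gave 0 in Chlorpyrifos Medium, 2283 in Malathion Medium, 1 in Mixture Low, and 35 (High) and 1288 (Medium) for chlorpyrifos against malathion.

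With the slide as a fixed block the counts were 10 in Chlorpyrifos High, 2 in Chlorpyrifos Medium, 605 in Malathion High, 27 in the pLD pair, 4932 in Mixture High, 4 in Mixture Low, 1709 in Mixture Medium, 2529 (High) and 1048 (Medium) for departures, 1350 for controls, 416 for chlorpyrifos against malathion (High), and 809 (malathion) and 6108 (mixture) for trends. As a random block (correlation 0.111) it gave 13 in Chlorpyrifos High, 3 in Chlorpyrifos Medium, 1 in the pLD pair, 809 in Mixture Medium and 916 departures (Medium). Slide and position together gave 2 in Chlorpyrifos High, 0 in Chlorpyrifos Medium, 393 in Malathion High, 2 in Malathion Low, 1263 in Malathion Medium, 26 in the pLD pair, 4 in Mixture Medium, 1559 departures (High), 777 for controls, 420 for chlorpyrifos against malathion (High), and trends of 1, 465 and 1974. Position alone gave 2 in Chlorpyrifos High, 0 in Chlorpyrifos Medium, 2 in Malathion Low, 2620 in Malathion Medium, 688 in Mixture High, 74 in Mixture Medium, 31 for chlorpyrifos against malathion (High), and trends of 2 (chlorpyrifos) and 1203 (mixture). The scan day gave 3510 in Mixture High, 1412 in Mixture Medium, 870 departures (Medium), and trends of 14 (chlorpyrifos) and 4878 (mixture). Slides holding both groups, with fewer arrays, gave 13 in Chlorpyrifos High, 4 in Chlorpyrifos Medium, 0 in Malathion Low, 0 in Mixture High, 0 in Mixture Low and 7 in Mixture Medium.

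Fitting only the arrays of the experiments compared, with fewer arrays and only their own spread, gave 14 in Chlorpyrifos High, 2427 in Malathion High, 0 in Malathion Low, 16 in Mixture High, 0 in Mixture Low, 0 in Mixture Medium, 393 for chlorpyrifos against malathion (High) and 159 for the mixture trend. Array quality weights gave 3097 in Chlorpyrifos High, 130 in Chlorpyrifos Medium, 57 in Malathion Low, 7509 in Malathion Medium, 1 in the pLD pair, 1500 in Mixture Low, 6024 in Mixture Medium, departures of 7637 (High) and 4313 (Medium), 16834 for controls, 1455 (High), 8 (Low) and 7068 (Medium) for chlorpyrifos against malathion, and 3024 for the chlorpyrifos trend. An intensity trend in the prior variance gave 9 in Chlorpyrifos High and 1 in the pLD pair. Without the dim arrays there were 13 in Chlorpyrifos High, 7 in Chlorpyrifos Medium, 2688 in Malathion High, 818 in Mixture Medium, 968 departures (Medium) and 248 for chlorpyrifos against malathion (High). Brightness as a covariate gave 14 in Chlorpyrifos High, 2 in Chlorpyrifos Medium, 3856 in Mixture High, 669 in Mixture Medium, 468 for chlorpyrifos against malathion (High) and 5071 for the mixture trend. The share of probes well above background gave 8 in Chlorpyrifos High, 1209 in Mixture High and 1987 for the mixture trend. Testing only probes well above background on all arrays gave 0 in Chlorpyrifos Medium, 2 in Malathion Low, 2739 in Malathion Medium, 1 in the pLD pair, 0 in Mixture Low, 5944 for controls, 59 (High) and 1735 (Medium) for chlorpyrifos against malathion, and trends of 5 (chlorpyrifos) and 5164 (malathion). With no filter there were 4373 in Mixture High, 179 in Mixture Medium and 6459 for the mixture trend, and with non-uniform spots kept 4 in Mixture Low.

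The replicate numbers do not pair the samples: same-number pairs correlated over 0.1 in 3 of 20 (mixture), 5 of 19 (chlorpyrifos), 3 of 18 (malathion) and 1 of 3 (pLD). With the replicate block the counts were 1 in Chlorpyrifos High, 0 in Chlorpyrifos Medium, 49 in Malathion High, 0 in Malathion Low, 919 in Malathion Medium, 6 in Mixture High, 0 in Mixture Low, 0 in Mixture Medium, departures of 2387 (High) and 0 (Medium), 0 (High) and 1042 (Medium) for chlorpyrifos against malathion, and trends of 0, 2433 and 5. CUST_21187_PI417904088 in Chlorpyrifos High missed the threshold in this fit alone (log2 2.39, adjusted p = 0.259). The controls could not be compared with the replicate block. That block was fitted to only the arrays of the experiments compared, with fewer arrays and only their own spread. These counts and this miss therefore do not isolate the replicate number.

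Leaving out 1 array gave counts of 3 to 159 in Chlorpyrifos High, 0 to 4 in Chlorpyrifos Medium, 2208 to 5177 in Malathion High, 1 to 10 in Malathion Low, 0 to 1 in the pLD pair, 711 to 2644 in Mixture High, 0 to 9 in Mixture Low and 47 to 807 in Mixture Medium. Scaling moved the share of higher calls further for chlorpyrifos against malathion (42.0% at Medium and 49.2% at High in the authors' deposited table, 17.1% at Medium with normexp), for departures at High (83.7% with normexp), for the malathion trend (42.5% in the authors' deposited table, 36.0% with normexp) and in Mixture Medium (25% with normexp). The median change of all probes was 0.12 in Malathion Medium; with normexp it was -0.19 in Chlorpyrifos Low, 0.28 in Malathion High, -0.28 in the pLD pair, -0.35 in Mixture Low and -0.38 in Mixture Medium. The gene lists, camera with an estimated correlation and 1 probe per gene name were not run, because the probes could not be paired with gene names.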

Other observations

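The scores reported here, except the test of Mixture High, were chosen after the counts of called probes had been seen. On the Malathion Medium score, as a percent of its size in Malathion Medium, the change against the group's own control was -1.07 ± 8.53 (SE) in Malathion Low and 86.1 ± 8.34 in Malathion High. It was -34.9 ± 8.65 in Chlorpyrifos Medium, -46.7 ± 10.5 in Mixture High and -18.6 ± 8.20 in the pLD pair. The score was higher in Malathion Medium than in the controls on all 4 shared slides, by 0.61 to 0.95. A score built in the same way for 3 other comparisons was above the controls on 4 of 5 shared slides in Chlorpyrifos High (lowest -0.15), 3 of 4 in Mixture Medium (lowest -0.11) and both in Mixture High (0.46 and 0.47).

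All 4 probes called higher in Chlorpyrifos High had positive differences in the pLD pair, none past the threshold: 1.44 for CUST_21187_PI417904088 (adjusted p = 0.0622), 1.19 for CUST_39901_PI417904088 (adjusted p = 0.918), and 1.16 and 0.89 for the remaining pair (adjusted p = 0.918 and 0.723). These were looked up after the Chlorpyrifos High calls had been seen.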
